A study of Danio rerio with 16 samples.

How the data were processed

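The samples were single-cell suspensions of wild-type zebrafish telencephalon (the protocol speaks of dissected forebrain tissue, dissociated with papain), made into 10x 3' v2 libraries. The authors deposited 1 matrix per library, and its values are raw UMI counts per gene and barcode, not normalised, per the file headers and the whole-number values. All 16 matrices hold the same 32191 Ensembl genes, with barcodes already selected by cell calling. The submitters' processing notes give Cell Ranger 2.1.0 and build GRCz10 for every library, whereas the matrix headers give software version 3.0.1 for 6dpf samples 1 to 3 and 3.1.0 for 6dpf samples 4 to 8 and all 15dpf samples. The adult headers give no version and an older gene file layout. The 3.0.1 libraries are all of 6dpf, so only 6dpf samples 4 to 8 and the 15dpf samples allow a comparison within 1 version. The genome annotation release is not given in the sources used here. Gene symbols come from the deposited gene files, where 3687 gene IDs share a symbol with another ID; those were tested by ID.

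Cells with under 400 detected genes (5464 of 70718 barcodes) or over 15% of UMIs from mitochondrial genes (70) were left out. Per library the gene minimum removed 215 to 810 barcodes at 6dpf, 197 to 292 at 15dpf and 84 to 295 in adults. The libraries held 1818 to 4441, 3706 to 4966 and 6516 to 7156 barcodes in the same order. Doublets were scored with scanpy's Scrublet per library, and the highest-scoring 0.8% of cells per 1000 barcodes were removed (2853), as planned; Scrublet's own threshold marked 0 to 8 cells per library. A first run used a rewritten version of the score, which removed whole rare cell types, and it was replaced with scanpy's after that had been seen. The 62331 kept cells were log-normalised, reduced to 2000 variable genes and 40 principal components, and clustered with 20 neighbours by the Leiden method at resolution 1, without batch integration. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

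Clusters were named from marker lists fixed before the data were examined. A class needed at least 3 markers detected in 10% of the cluster's cells with a mean log2 fold of at least 1, and no class with at least 0.5 of its score could have more detected markers. Neurons were split by their transmitter genes. An inhibitory name needed at least 200 CPM of GABA genes and at least 2 times the level of glutamate transporter genes. An excitatory name needed at least 2 times the level of GABA genes, with no minimum CPM. Both needed at least 3 of their own markers in 5% of the cells. This naming rule was revised several times after the contents of clusters had been seen and before any stage test: an earlier version called cluster 30 a neuron, and the limit of 0.5 was set knowing that it names cluster 30 and leaves clusters 28 and 31 unnamed. Oligodendrocytes and their precursors were merged into 1 class in the same way. Class names therefore stand for cells that resemble a type by those markers. A cluster whose 10 leading genes held more markers of another class lost its name, and neurons then joined those without a named transmitter. Shallow clusters led by none of their own markers were treated alike.

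UMI counts were summed per sample and class, over samples with at least 20 cells, and all 3 stages were fitted together with edgeR's quasi-likelihood test after TMM scaling and the default low-count filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and the CPM of single genes are means over samples on the TMM-scaled totals of the tested genes. Pooled CPM, and the summed CPM of a list, are taken over all UMIs of the class without that scaling. For radial glia 4 samples of 6dpf, 4 of 15dpf and 2 of adults passed the minimum. The class by stage interaction used the sample as a block. Named genes follow a rule fixed before the data were examined: for each class and contrast, the 5 largest rises and the 5 largest falls among called genes whose samples do not overlap between the stages, whose mean over the fit is at least 5 on the log2 CPM scale, whose CPM in the class is at least that of all kept cells at the stage where it is higher, and whose symbol is no clone name; and up to 4 members per gene list. Clone prefixes beyond those first listed and symbols ending in "(1 of many)" were left out after the data had been seen. Chosen outside this rule, after their values had been seen, were the interaction genes, and the genes of the light, clock and p53 lists; microglial genes follow the rule under a minimum chosen later.

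Gene lists, 21 in all, were fixed beforehand: cell cycle, Notch signalling, glial uptake and metabolic support, synaptic vesicle and release, ionotropic glutamate receptors, GABA receptors and chloride transport, neuropeptides, neuronal immaturity and axon growth, voltage-gated channels, myelin, immediate early genes, heat shock, antigen presentation and interferon, complement and lysosome, microglial identity and sensing, cholesterol and lipid synthesis, mitochondrially encoded genes, cytoplasmic ribosomal proteins, globins, thyroid hormone response, and neuron maturation. They were tested with camera on voom values (preset correlation 0.01, and an estimated correlation as an alternative) and with fry, and 102 of the tests had at least 3 tested genes in the list.

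Class shares, the inhibitory share and the cycling share were compared with exact two-sided permutation tests on the difference of means, adjusted over the 14 classes with at least 100 cells. The smallest exact p is 0.00202 for 15dpf against 6dpf (495 splits), 0.0222 for adults against 6dpf (45 splits) and 0.0667 for adults against 15dpf (15 splits), so with this test the last contrast is described by values only. A cycling cell had UMIs of at least 2 genes of the cell cycle list after thinning to 1000 UMIs; shallower cells were left out (50, 23 and 35 radial glia and progenitors, and 1182, 350 and 901 excitatory neurons, at the 3 stages). Ratios that rest on 1 to 3 UMIs carry 95% exact (Clopper-Pearson) intervals, and a fold against 0 UMIs uses a floor of 3 UMIs over the stage; both cover counting error only.

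The test was checked on simulated data made from these samples with 200 changed genes: it recovered 81.3% to 90.5% of genes changed 3-fold, 88.1% to 98.5% of genes changed 4-fold and 96.8% to 100% of genes changed 8-fold, and called 3 to 13 unchanged genes. The simulated libraries were drawn independently, with the same mean at all stages for unchanged genes. Libraries that are alike and a changing mix of clusters were thus not covered by this check. Other settings fixed before the data were examined were RLE scaling, DESeq2, no low-count filter, 4 adult samples, a guard against free RNA, thinning to 1000 UMIs, at least 800 genes per cell, doublets kept, resolutions 0.5 and 2, a replicate block and leaving out each sample. Added after seeing the data were libraries that are alike summed (limit on chi-square per degree of freedom 6), the 3.1.0 libraries alone, leaving out 6dpf samples 6 and 7, leaving out clusters led by tubb5, a minimum of 5 microglia, clusters shared by the stages (at least 150 cells of each), the light, clock and p53 lists, and neurons without a named transmitter by cluster number. Splits of the samples were run for whole classes, and later for alike libraries summed and within each shared cluster. The limit for the mix of clusters, more genes than in any other split of a cluster's own samples, was set after those counts had been seen. That grouping by cluster number was at first entered as the main one after the 14-class result had been seen and was then put back as an alternative. In the handling test of the closing section the limits 1.5 and 2 were set beforehand, but the verdict for a ratio of 2 or more was added to the program after the ratios had been seen, and it changed neither verdict. No genome was used, and isoforms and sequence variants were not analysed here.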

Results

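Single cells of the zebrafish telencephalon were profiled at 3 stages, with 8 libraries at 6 days post fertilisation (6dpf), 4 at 15dpf and 4 of adults. The adult titles carry 2 numbers, and adult libraries that share the first were summed, which gave n = 8, 4 and 2 samples. Total UMI counts per library ranged from 3066354 to 10480732 at 6dpf, from 8630572 to 10613082 at 15dpf and from 16094242 to 19150814 in adults. The median UMI count per barcode ranged from 1096 to 1648, from 1874 to 2052 and from 1947 to 2574 in the same order, so depth rose with stage. After quality filters 62331 cells remained, 21362 at 6dpf, 15926 at 15dpf and 25043 in adults, in 42 clusters. The minimum of detected genes removed a larger part of the barcodes at 6dpf than at the later stages, and all shares are of kept cells. No protocol says that libraries came from separate animals, so the p-values measure the spread between these samples only. Among libraries of 1 stage, 7 pairs had profiles far closer than the rest (chi-square per degree of freedom from 2.604 to 5.00, against 9.22 to 60.2 in the other pairs), and summing them left 5, 2 and 2 samples.

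Excitatory neurons were the largest class, with 27587 cells in 15 clusters, followed by inhibitory neurons with 18802 cells in 8 clusters. Neurons without a named transmitter formed 5 clusters with 5620 cells and may still carry transmitter genes. In 3 of these clusters the leading genes held more markers of another class, which removes a transmitter name. The class is thus not 1 cell type. Proliferating progenitors numbered 2759, habenula-like neurons 1853, radial glia 1301 and committed precursors 1154. Oligodendrocyte lineage cells numbered 624, endothelial cells 550, microglia or macrophages 380 and mural cells 137, and 3 clusters with 1564 cells stayed unnamed. Class names stand for cells that resemble each type by a fixed list of markers. The habenula-like class held 519 adult cells, all from adult sample 1 and none of the 12235 cells from adult sample 2, which allows a share of up to 0.0314% there by Wilson's 95% interval.

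Excitatory neurons made up 32.3% ± 3.88 (SD, n = 8) of the cells at 6dpf, 40.3% ± 1.75 (n = 4) at 15dpf and 56.2% ± 2.28 (n = 2) in adults. Inhibitory neurons made up 30.7% ± 3.70, 33.7% ± 3.40 and 27.5% ± 1.06. Proliferating progenitors made up 6.15% ± 4.51, 6.43% ± 1.38 and 0.424% ± 0.173, and committed precursors 2.396% ± 1.32, 3.24% ± 0.155 and 0.254% ± 0.0934. Oligodendrocyte lineage cells stood at 0.182% ± 0.201, 0.0765% ± 0.0737 and 2.28% ± 0.678, and endothelial cells at 0.195% ± 0.112, 0.384% ± 0.0267 and 1.79% ± 0.281. Radial glia made up 1.43% ± 1.02, 1.01% ± 0.401 and 3.08% ± 0.0642, and microglia 0.499% ± 0.387, 0.306% ± 0.0655 and 0.988% ± 0.0941. Some of these directions turned under other settings: with doublets kept adults differed from 15dpf by -4.06 percentage points in excitatory neurons, and with at least 800 genes per cell by -2.04 in radial glia and 1.12 in inhibitory neurons. Against 6dpf the same 800-gene limit gave -9.97 points for adult radial glia, 5.71 for inhibitory neurons and -0.405 for microglia. Under that limit the radial glia class held 2010 cells in place of 1301, so its members differed.

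None of the 14 class shares differed between 15dpf and 6dpf after Benjamini-Hochberg adjustment of exact two-sided permutation tests (lowest adjusted p 0.0848), and 4 had an unadjusted exact p under 0.05. Excitatory neurons were 8.05 percentage points higher at 15dpf (exact p 0.00606), with no overlap between the samples, which chance gives in 0.404% of splits. Endothelial cells (exact p 0.0182), mural cells (exact p 0.0222) and neurons without a named transmitter (exact p 0.0242) were the other 3. The exact p-values and chance shares, here and for the inhibitory and cycling shares, count the larval libraries as independent. With alike libraries summed the smallest exact p is 0.0476 for either later stage against 6dpf and 0.333 for adults against 15dpf. Without 6dpf sample 7, 3 of the shares passed after adjustment. Between adults and 6dpf 0 of the 14 shares passed (lowest adjusted p 0.0622) and 7 had an unadjusted exact p under 0.05. Of these, 5 sat at the smallest exact p the design allows, 0.0222, among them excitatory neurons (23.9 points higher in adults) and oligodendrocyte lineage cells (2.09 points higher). In 7 of the 14 classes the adult and 6dpf samples did not overlap, which chance gives in 4.44% of splits per class. Between adults and 15dpf the smallest exact p is 0.0667, so this test could not reach 0.05, and 12 of 14 classes did not overlap, against a chance share of 13.3% per class.

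Neurons without a named transmitter fell apart by stage when their clusters were counted separately. Cluster 10, led by mab21l1 and pdyn, made up 6.57% of cells at 6dpf, 5.38% at 15dpf and 0.111% in adults. Cluster 14, led by trh and otpb, made up 5.28%, 2.90% and 1.45%, and cluster 24, led by dbx1a, 2.199%, 1.72% and 0.464%. Cluster 36, led by pyya, made up 1.07%, 0.705% and 0.151%. Cluster 37, led by pld6 and nrgnb, held 248 adult cells, 1 cell at 6dpf and none at 15dpf, and made up 0.992% of adult cells. This split was made after the result over 14 classes had been seen. Over the 18 groups it gives, 9 of the adult against 6dpf differences had an adjusted exact p of 0.0444 (11 unadjusted under 0.05), and that count rests on how the neurons were grouped. Between 15dpf and 6dpf the same grouping gave 0 of 18 after adjustment and 4 unadjusted.

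**Figure D1:**
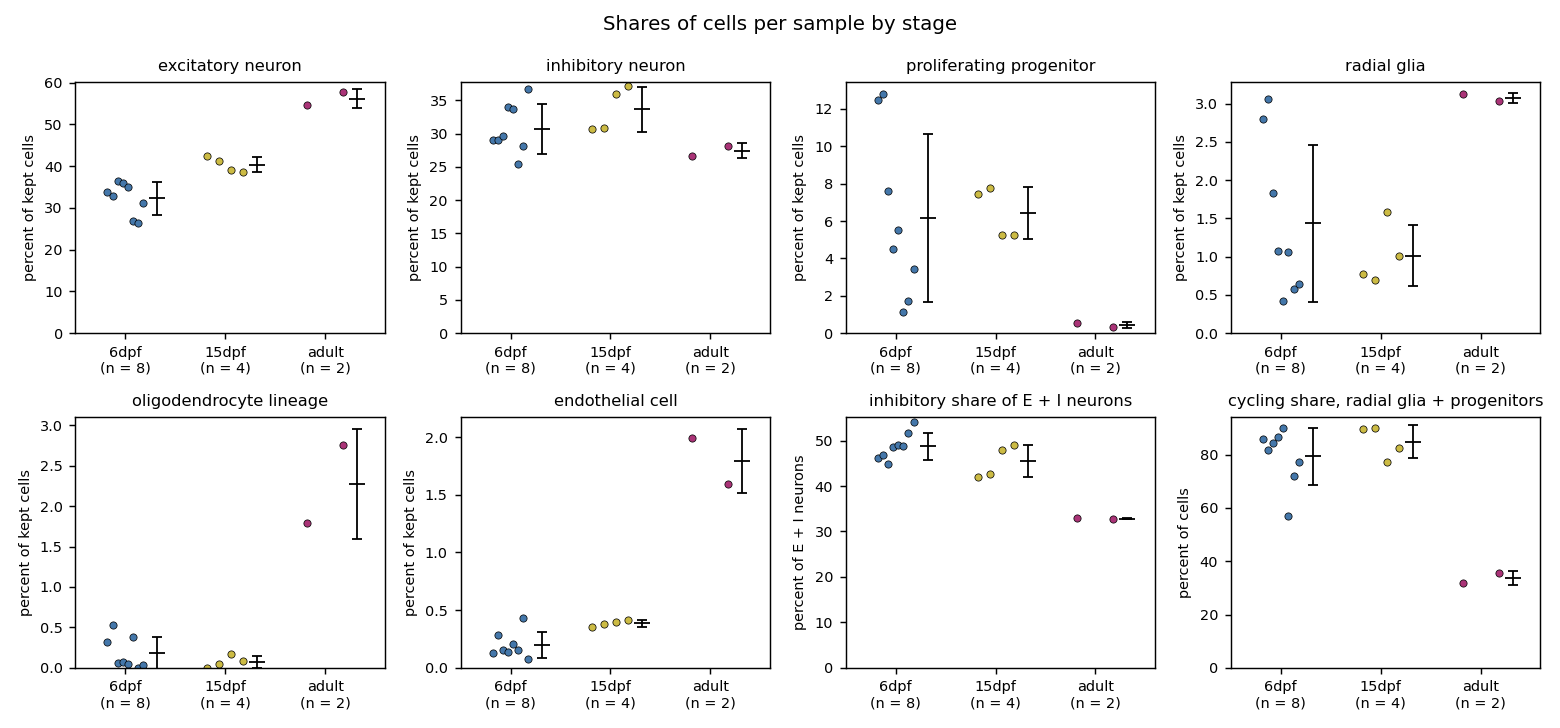
Share of kept cells per sample in percent at 6dpf (n = 8), 15dpf (n = 4) and in adults (n = 2), for 6 classes and for the inhibitory and cycling shares, with the mean and SD beside the points. Excitatory neurons averaged 32.3%, 40.3% and 56.2%, and proliferating progenitors 6.15%, 6.43% and 0.424%.

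Inhibitory neurons made up 48.8% ± 2.96 (SD, n = 8) of excitatory plus inhibitory neurons at 6dpf, 45.4% ± 3.56 (n = 4) at 15dpf and 32.8% ± 0.0390 (n = 2) in adults. The naming set a minimum level for GABA genes but none for glutamate transporter genes, so these shares also rest on that rule. The adult share differed from 6dpf by -15.9 percentage points (exact two-sided permutation p 0.0222, the smallest possible) and from 15dpf by -12.6 points. The drop was smaller under other filters: with at least 800 genes per cell the difference from 6dpf was -5.86 points (exact p 0.244), and with doublets kept -5.75 points (exact p 0.0444), and the difference from 15dpf was -3.64 and -2.70 points. Between 15dpf and 6dpf the share differed by -3.32 points (exact p 0.113), whereas among the libraries whose headers give software version 3.1.0 (5 at 6dpf, 4 at 15dpf) the difference was -4.96 points (exact p 0.0238).

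Among radial glia and proliferating progenitors together, the share of cells with UMIs of at least 2 cell cycle genes was 79.4% ± 10.6 (SD, n = 8) at 6dpf, 85.0% ± 6.16 (n = 4) at 15dpf and 33.6% ± 2.65 (n = 2) in adults, with every cell thinned to 1000 UMIs. Adults differed from 6dpf by -45.8 percentage points (exact two-sided permutation p 0.0222) and from 15dpf by -51.4 points. Most of this came from the mix of the 2 classes: proliferating progenitors showed 92.5%, 93.2% and 92.2%, and radial glia 34.2%, 33.7% and 25.3%, and the adult cells were mostly radial glia (771, with 107 progenitors). Excitatory neurons, which should not cycle, showed 8.50% ± 2.68, 4.101% ± 0.327 and 3.56% ± 0.822 at the same depth. Between 15dpf and 6dpf the share differed by 5.59 points (exact p 0.382). Progenitors were named by markers of proliferation, so a high cycling share in them is partly fixed by the naming. Phase was not called, and a UMI of a cell cycle gene can come from free RNA.

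Radial glia gained cyp19a1b, the brain aromatase gene, which measured 2.54 ± 3.22 CPM (SD, n = 4) at 6dpf, 38.5 ± 15.15 (n = 4) at 15dpf and 3016 ± 409 (n = 2) in adults. Its rise from 15dpf to adults was 6.41 ± 0.27 (log2, SE), with an edgeR adjusted p of 3.2e-12. The calcium-binding protein gene s100b rose at both steps, from 36.9 CPM to 276 CPM and 1951 CPM. At 15dpf cyb5r2, cxcl12b, enkur, krt8 and cyp19a1b were the top risers against 6dpf, and abca1a, slc43a2b, cbsb, arrdc2 and lpl the top fallers. Only 2 UMIs at 6dpf stood for cyb5r2, enkur and cyp19a1b, whose pooled 15dpf over 6dpf ratios were 39.7 (95% exact interval 10.4 to 338), 19.9 (4.91 to 174) and 17.3 (4.196 to 152). The log2 rise was 4.05 ± 0.78 for cxcl12b and 3.80 ± 0.57 for krt8, and the fall was -3.61 ± 0.54 for abca1a, -3.53 ± 0.65 for slc43a2b, -3.11 ± 0.45 for cbsb, -2.91 ± 0.56 for arrdc2 and -2.83 ± 0.38 for lpl. In all, 581 of 3120 tested genes were called between 15dpf and 6dpf, 294 higher and 287 lower. The count was 171 with alike libraries summed, 142 with cells thinned to 1000 UMIs, and 115 among the 3.1.0 libraries, where 1 sample of 6dpf passed the minimum of 20 cells and was assumed to vary like the others (a fit added after the data had been seen). There cxcl12b, enkur, cyp19a1b, arrdc2 and lpl no longer passed, which with 1 sample of 6dpf does not show that their change was smaller. Markers of other cell types rose in 15dpf radial glia too: 2 of 2 ependymal or ciliated (median 3.05), 2 of 2 oligodendrocyte precursor (1.94), 1 of 2 habenula (1.40), and the only tested oligodendrocyte (2.30), epithelial or skin (3.80) and preoptic (1.40) markers. So did 1 of 6 committed precursor or immature neuron markers (median 0.26). With at least 800 genes per cell krt8 changed sign, and cxcl12b, enkur and arrdc2 no longer passed. Without 15dpf sample 3, enkur rose by 2.75 and no longer passed. Both cxcl12b and krt8 were far higher in endothelial cells of 15dpf (1894 CPM and 2184 CPM pooled) than in radial glia (78.1 CPM and 67.7 CPM).

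Against 15dpf, adult radial glia gained icn, rgs5b, hsd17b3, cyp19a1b and b2m and lost ssuh2rs1, cth, ntn1b, rgcc and gch2. No UMI of icn was found at 15dpf, so its pooled level of 185 CPM in adults was at least 35.5-fold higher, from a floor of 3 UMIs over the stage. Single UMIs at 15dpf stood for rgs5b (ratio 161, 95% exact interval 28.9 to 6383), and 2 UMIs for hsd17b3 (ratio 109, interval 30.0 to 899). The log2 rise of b2m was 6.21 ± 0.38, and the fall was -5.28 ± 0.53 for ssuh2rs1, -3.64 ± 0.82 for cth, -3.62 ± 0.58 for ntn1b, -3.59 ± 0.40 for rgcc and -3.53 ± 0.74 for gch2. In all, 502 of 3120 genes were called, 314 higher and 188 lower in adults; alike libraries summed gave 268, thinned cells 164 and at least 800 genes per cell 1277. Adult endothelial cells held more icn (pooled values, 6468 CPM against 185 CPM in radial glia) and more b2m (4147 CPM against 757 CPM), and adult mural cells more rgs5b (808 CPM against 280 CPM). Markers of other cell types also rose in adult radial glia: 2 of 2 ependymal or ciliated (median 2.17), 2 of 3 of neurons of any kind (1.49), 1 of 2 habenula (1.02), and the only tested mural (7.30), epithelial or skin (2.76) and erythrocyte (1.78) markers. So did 2 of 6 committed precursor or immature neuron markers (median 0.48). The 2 radial glia clusters split by stage: cluster 27 held 6 cells of 6dpf, 26 of 15dpf and 769 of adults, and cluster 32 held 364, 134 and 2. No comparison within these clusters was run.

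Excitatory neurons at 15dpf had more bag3 (171 CPM against 35.9 at 6dpf), uts1 (76.0 against 15.7), akap11 (220 against 54.8) and pvalb7 (192 against 45.3) than at 6dpf. Less abundant at 15dpf were dcps (10.0 CPM against 63.9), MCRIP2 (16.3 against 78.1), mdm2 (24.9 against 103), emx2 (17.1 against 68.2) and lhx1a (38.7 against 152). The log2 change with its SE was 2.28 ± 0.27 for bag3, 2.23 ± 0.30 for uts1, 2.03 ± 0.13 for akap11, 2.02 ± 0.24 for pvalb7, -2.73 ± 0.45 for dcps, -2.22 ± 0.24 for MCRIP2, -2.001 ± 0.32 for mdm2, -1.94 ± 0.25 for emx2 and -1.93 ± 0.34 for lhx1a. The symbol erv, a retroviral element, had the largest rise (3.93 ± 0.50), but copies of such elements share reads. In all, 948 of 10807 genes passed the edgeR test, 367 higher and 581 lower at 15dpf (n = 4) than at 6dpf (n = 8). With alike libraries summed 295 passed, and among the 3.1.0 libraries alone 1110.

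Excitatory neurons of adults had more cox8b (767 CPM against 63.9 at 15dpf), map1ab (746 against 104), c1ql3b (702 against 101), eif4ebp3l (222 against 34.6) and atp1a3b (107 against 17.0). The RNA-binding protein gene igf2bp1 measured 131 CPM at 6dpf, 72.6 at 15dpf and 0.755 in adults. Other losses were grm2a (68.8 to 2.37 CPM), barhl2 (42.8 to 1.58), crhbp (127 to 4.79) and nppb. A single UMI of nppb in adults gave a pooled 15dpf over adult ratio of 942 (95% exact interval 168 to 37306), and nppb no longer passed without either adult sample. The log2 change with its SE was 3.58 ± 0.50 for cox8b, 2.84 ± 0.22 for map1ab, 2.80 ± 0.34 for c1ql3b, 2.68 ± 0.32 for eif4ebp3l, 2.65 ± 0.49 for atp1a3b, -6.57 ± 0.32 for igf2bp1, -4.84 ± 0.51 for grm2a, -4.75 ± 0.44 for barhl2 and -4.71 ± 0.57 for crhbp. In all, 1342 genes passed, 757 higher and 585 lower in adults (n = 2), 841 with alike libraries summed and 823 without adult sample 1. Clusters 1, 7, 11, 12, 19 and 33 held mostly adult cells and clusters 2, 6, 9, 15 and 17 mostly larval cells, so class means also reflect which neurons were sampled.

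Inhibitory neurons at 15dpf had more bag3 (181 CPM against 38.4 at 6dpf), trh (96.0 against 28.7), tubb2 (37.0 against 11.1), gria1a (413 against 130) and atf3 (555 against 173). They had less dcps (10.8 CPM against 68.9), histh1l (292 against 1586), cry-dash (24.0 against 119), selj (23.6 against 105) and gadd45bb (38.7 against 161). The log2 change with its SE was 2.24 ± 0.22 for bag3, 1.72 ± 0.22 for trh, 1.69 ± 0.21 for tubb2, 1.68 ± 0.24 for gria1a, 1.68 ± 0.18 for atf3, -2.74 ± 0.45 for dcps, -2.44 ± 0.48 for histh1l, -2.28 ± 0.24 for cry-dash, -2.13 ± 0.23 for selj and -2.05 ± 0.17 for gadd45bb. In all, 629 of 10099 genes passed the edgeR test, 256 higher and 373 lower at 15dpf, 192 passed with alike libraries summed and 729 among the 3.1.0 libraries alone.

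Inhibitory neurons of adults had more galn (3453 CPM against 50.8 at 15dpf), nrgnb (507 against 28.1), fosaa (112 against 9.16), egr2b (574 against 94.98) and pyya (1078 against 195). Adult values of galn varied as much as their mean (SD 3173, n = 2), and with at least 800 genes per cell or at resolution 2 galn no longer passed (0.90 and 1.06). Without adult sample 1 pyya rose by 2.397 and no longer passed. The vesicle protein gene synpr measured 471 CPM at 6dpf, 786 at 15dpf and 8.22 in adults, and igf2bp1 measured 126, 72.9 and 0.321. Also lower in adults were hsp70.1 (7167 to 765 CPM), ing4 (314 to 37.5) and dnmt3ab (220 to 35.2). The log2 change with its SE was 6.06 ± 1.02 for galn, 4.17 ± 0.23 for nrgnb, 3.61 ± 0.36 for fosaa, 2.59 ± 0.23 for egr2b, 2.47 ± 0.65 for pyya, -7.66 ± 0.36 for igf2bp1, -6.57 ± 0.39 for synpr, -3.23 ± 0.53 for hsp70.1, -3.06 ± 0.22 for ing4 and -2.64 ± 0.24 for dnmt3ab. In all, 1515 genes passed, 830 higher and 685 lower in adults, and 1009 without adult sample 2. Clusters 3 and 4 held mostly adult cells and clusters 0, 8 and 18 mostly larval cells.

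In 5 neuron clusters with at least 150 cells of each stage (6, 16 and 21 excitatory, 13 and 23 inhibitory), 104 to 299 genes were called per cluster between 15dpf and 6dpf and 198 to 410 between adults and 15dpf. Of the class calls that a cluster could test, 27.9% to 63.3% were called there too at 15dpf and 24.9% to 65.3% in adults. Their sign was kept in 95.8% to 98.2% at 15dpf and 85.6% to 97.0% in adults. Adult libraries differ from all others in file format as well as in age, so format and age cannot be told apart for adult comparisons within a class.

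Immediate early genes were higher in adults than at 15dpf in all 3 classes, with fosb, btg2, junba and junbb leading in radial glia. Of the tested members 11 of 15 rose in radial glia (median log2 change 1.69), 7 of 18 in excitatory neurons (0.89) and 6 of 17 in inhibitory neurons (0.75), and the counts adjusted over the list alone were also 11, 7 and 6. Their adjusted p from camera with its preset correlation was 2.0e-10, 3.1e-06 and 7.1e-06, and 0.144, 0.146 and 0.144 with an estimated correlation. From 6dpf to 15dpf 2, 1 and 1 members rose and 0, 2 and 2 fell (adjusted over the list alone 2, 1 and 1 rose and 0, 3 and 2 fell). Heat shock genes were lower in adults than at 15dpf. Between these stages 5 of 14 fell in radial glia (median -0.87), 7 of 15 in excitatory neurons (-0.84) and 9 of 15 in inhibitory neurons (-1.33), with adjusted p 2.1e-06, 8.7e-06 and 1.6e-07 and, with an estimated correlation, 0.144, 0.181 and 0.181. The counts adjusted over the list alone were 5, 7 and 9 fallen, with 0, 1 and 1 risen. From 6dpf to 15dpf 3 heat shock genes rose in excitatory and 5 in inhibitory neurons (the same counts adjusted over the list alone), with estimated-correlation adjusted p 0.375 and 0.181, while in radial glia 2 rose and 3, among them hspa8, hspe1 and hspd1, fell.

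**Figure D2:**
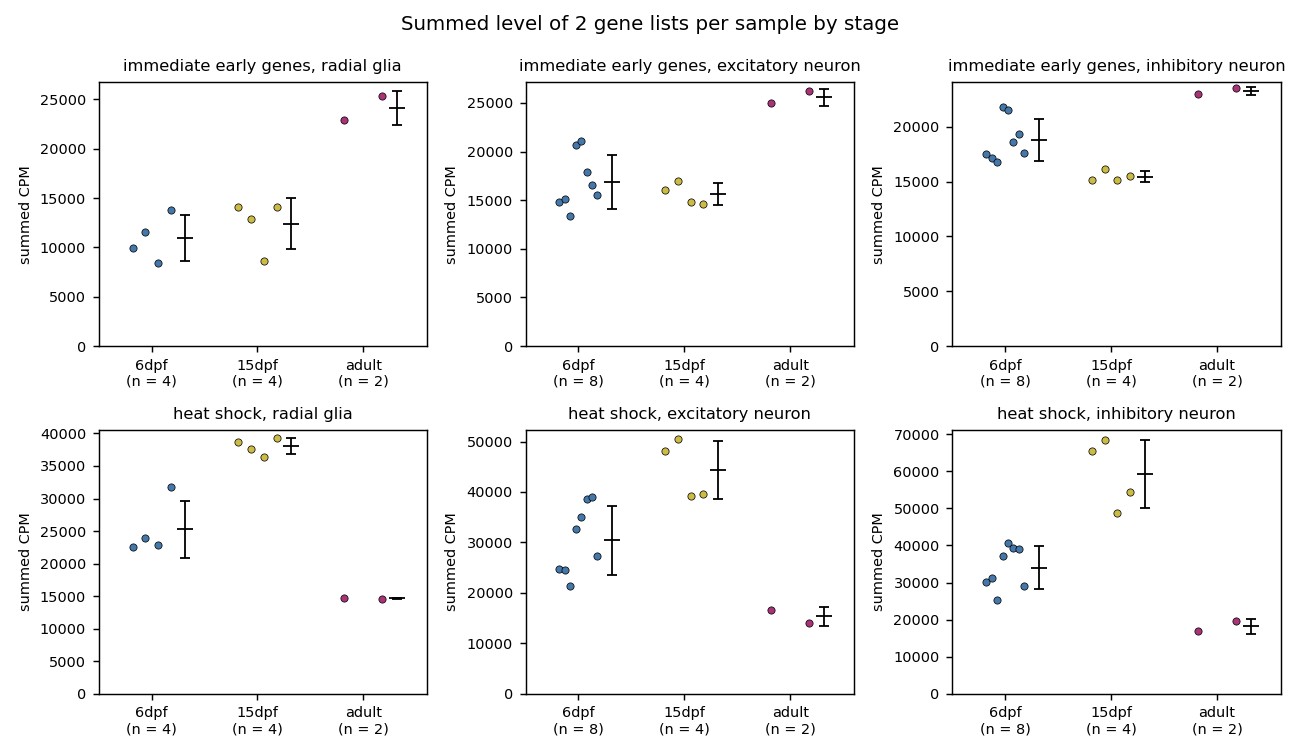
Summed CPM of the immediate early and heat shock lists per sample in radial glia, excitatory neurons and inhibitory neurons at the 3 stages, with the mean and SD beside the points. In excitatory neurons heat shock genes averaged 30425 CPM at 6dpf, 44322 CPM at 15dpf and 15373 CPM in adults.

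Antigen presentation and interferon genes were higher in adults than at 15dpf, with 3 of 4 in radial glia, 5 of 8 in excitatory and 6 of 8 in inhibitory neurons (adjusted over the list alone 3, 6 and 6), led by b2m, b2ml, mhc1zba and cd74a. In each neuron class 1 member fell, mhc1uba in the excitatory. Their estimated-correlation adjusted p was 0.144, 0.199 and 0.181, against 9.4e-04, 0.0072 and 9.8e-04 with the preset. Of 3 tested microglia or macrophage markers 2 rose in adult excitatory neurons (median 1.78) and 0 passed in inhibitory neurons (median 1.38). Of the cholesterol and lipid synthesis genes 6 of 12 rose from 6dpf to 15dpf in radial glia, such as sqlea, msmo1, hmgcs1 and cyp51, and 4 of 13 in excitatory neurons (the same adjusted over the list alone; estimated-correlation adjusted p 0.144 and 0.376). In inhibitory neurons 2 of 13 rose. Of the cell cycle genes 8 of 13 fell in adult radial glia (among them mcm5, mcm2 and rrm1, with ccnd1 rising; adjusted over the list alone 8 and 1; estimated-correlation adjusted p 0.6249), and at 15dpf 2 of 13 fell in radial glia, 4 of 8 in excitatory and 1 of 7 in inhibitory neurons (adjusted over the list alone 2, 4 and 1; estimated-correlation adjusted p 0.462, 0.144 and 0.270). Of the Notch signalling genes 3 of 11 rose in adult radial glia, her6, dla and her15.2, while 3 of 13 fell and 1 rose in adult excitatory and 4 of 14 fell and 1 rose in adult inhibitory neurons (adjusted over the list alone 3 risen, 3 fallen and 5 fallen; estimated-correlation adjusted p 0.181, 0.697 and 0.6249). In excitatory neurons 5 of 13 Notch genes fell at 15dpf (estimated-correlation adjusted p 0.444). Markers of radial glia (4 of 7, median -1.12) and of proliferating progenitors (2 of 3, median -1.02) fell in the same excitatory neurons, as did those of inhibitory neurons (4 of 10, -1.35), microglia (2 of 3, -1.57) and epithelial or skin cells (3 of 4, -3.21). Of the mitochondrially encoded genes 2 of 10 rose in adult radial glia, mt-cyb and mt-nd1 (adjusted over the list alone 2; estimated-correlation adjusted p 0.181). Ribosomal protein genes shifted slightly, with a median of -0.53 over 79 genes in 15dpf radial glia (7 called, 7 adjusted over the list alone; estimated-correlation adjusted p 0.181) and 0.41 in adult radial glia (3 called; estimated-correlation adjusted p 0.376).

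Of the neuronal immaturity and axon growth genes 4 of 19 fell in adult excitatory and 6 of 18 in adult inhibitory neurons (adjusted over the list alone 5 and 6, and estimated-correlation adjusted p 0.181 in both), led by tubb5, dpysl5a and sox4a, while 1 rose in each. Markers of committed precursors or immature neurons fell beside them, 5 of 13 in adult excitatory neurons (median -0.51). In adult inhibitory neurons 3 of 11 fell and 1 rose (median -0.04). Of the neuropeptides 9 of 19 rose in adult inhibitory neurons, among them sst1.1, pdyn and vip, while pnoca fell (adjusted over the list alone 9 and 1; estimated-correlation adjusted p 0.181), and in excitatory neurons 5 of 17 rose and 3 fell (adjusted over the list alone 5 and 4). Preoptic or hypothalamic markers rose beside them, 2 of 4 in adult inhibitory (median 0.84) and 2 of 3 in adult excitatory neurons (median 3.92). Of the synaptic vesicle genes 3 rose in each adult neuron class, vamp1 and snap25a in both (adjusted over the list alone 3 and 3), while the lists as a whole did not pass in excitatory or inhibitory neurons (camera adjusted p 0.129 and 0.659 with the preset, 0.476 and 0.803 with an estimated correlation). Of the neuron maturation list celf5a fell in both adult neuron classes (4 of 17 and 5 of 19 fell, the same adjusted over the list alone, and 0 and 1 rose), and at 15dpf 3 of 17 rose in excitatory neurons, camk2a and rbfox1 among them. Of the ionotropic glutamate receptors 2 of 15 rose at 15dpf in excitatory neurons (gria1a and grin2ab) and 1 of 15 in inhibitory neurons (gria1a), the same adjusted over the list alone (estimated-correlation adjusted p 0.181 and 0.168). GABA receptor genes gave gabra5 alone, which rose at 15dpf in excitatory neurons and in adults in inhibitory neurons. Voltage-gated channel genes gave scn2b, which rose at 15dpf and fell in adults in both neuron classes.

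Glial uptake and support genes moved both ways in radial glia: ptgdsb.1 and ptgdsb.2 fell at 15dpf (ptgdsb.1 from 17219 to 2725 CPM) and s100b rose, while in adults s100b, cx43 and glulb were among 4 that rose and slc1a3b among 2 that fell (adjusted over the list alone 4 and 2). Excitatory neurons held 503 CPM of ptgdsb.1 at 6dpf and 2.55 CPM at 15dpf. Of the myelin list cldn19 rose at 15dpf and fell in adult radial glia, and cnp fell in both adult neuron classes. Of the complement and lysosome genes psap rose in adult radial glia (1 of 8) and ctsd in adult inhibitory neurons (1 of 11; estimated-correlation adjusted p 0.330 and 0.432). The microglial identity list had 2 genes tested per class, of which si:ch211-212k18.7 rose in adult radial glia, and ptprc fell at 15dpf in both neuron classes and rose in adult excitatory neurons. Of the thyroid hormone response list dio2 rose in adult radial glia (9.07 to 240 CPM), and dio3b and klf9 rose in both adult neuron classes. Globin genes served as a check on free RNA: hbaa1 had 0 counts in larval neurons and 110 CPM in adult excitatory and 60.1 CPM in adult inhibitory neurons. Summed over the list, globins stood in excitatory neurons at 2.78 CPM at 6dpf, 168 CPM at 15dpf (649 CPM in sample 2, 4.64 to 9.42 CPM in the other 3) and 123 CPM in adults, and in inhibitory neurons at 12.15, 11.7 and 74.3 CPM. In proliferating progenitors they stood at 1097, 4668 and 5321 CPM (3.94 CPM in adult sample 1 and 10638 CPM in adult sample 2), and in adult endothelial cells at 1388 CPM. Over 102 list tests camera with a preset correlation of 0.01 gave 38 with an adjusted p under 0.05 and with an estimated correlation 0 (24 at an unadjusted p under 0.05). By fry 57 moved on balance one way and 87 changed in either direction. For neuropeptides in adult excitatory neurons the median and the mean change differed in sign (-0.20 and 0.27).

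Excitatory and inhibitory neurons differed in how 892 of 11427 genes changed between 6dpf and adults, by an edgeR test of the class by stage interaction with the sample as a block. For 562 genes the change was more positive in inhibitory neurons and for 330 in excitatory neurons. Many clusters of both classes held mostly adult or mostly larval cells, so these differences also reflect which neurons were sampled. The interaction was not tested within clusters. Among called genes with a mean of at least 5 on the log2 CPM scale, which leaves out nppb, npb, lhx1a, barhl2 and galn stood at the inhibitory end: lhx1a fell from 151 to 3.18 CPM in excitatory neurons and measured 38.62 and 56.7 CPM in inhibitory neurons (interaction 5.96 ± 0.32, log2 and SE). At the other end synpr fell from 466 to 8.23 CPM in inhibitory neurons and measured 5.90 and 34.5 CPM in excitatory neurons (-8.25 ± 0.24), and c1ql3b measured 42.4 and 705 CPM in excitatory but 19.3 and 22.3 CPM in inhibitory neurons (-3.76 ± 0.21).

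Microglia had too few larval cells for the planned minimum of 20 per sample, since the larval samples held 6 to 17. With a minimum of 5 cells, chosen after this was seen, cd74a rose from 12.9 CPM at 6dpf (n = 8) to 1190 CPM at 15dpf (n = 4) and 18931 CPM in adults (n = 2). Only 3 UMIs stood for cd74a at 6dpf (pooled ratio 110, 95% exact interval 36.9 to 539). The cathepsin gene ctsl.1 dropped from 1380 UMIs at 6dpf to 1 UMI at 15dpf (ratio 661, interval 118 to 26130). Adult microglia had more mhc2dab (log2 4.37 ± 0.57), b2m (3.53 ± 0.44) and cd74b (3.50 ± 0.43), and all 6 tested members of the antigen presentation list rose. In all, 68 of 705 genes passed between 15dpf and 6dpf (50 higher, 18 lower) and 51 between adults and 15dpf (27 higher, 24 lower), against 21 and 45 with alike libraries summed.

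Light-induced genes were lower at 15dpf than at 6dpf in both neuron classes. The list was written after cry-dash had been seen among the largest falls. In excitatory neurons tefa fell from 271 to 54.3 CPM, lonrf1l from 83.5 to 17.1 CPM and cry5 from 22.2 to 1.73 CPM, and in inhibitory neurons tefa fell from 498 to 177 CPM. In both classes 6 of 8 members fell (cry5, tefa, xpc, ddb2, neil1 and lonrf1l), with a median log2 change of -2.15 in excitatory and -1.48 in inhibitory neurons. For per2 no change passed in either class. The change of cry1aa was -0.88 in excitatory and -0.93 in inhibitory neurons (edgeR adjusted p 0.0024 and 3.6e-04). It missed only the log2 limit of 1. Of the core clock genes 3 of 23 fell in excitatory neurons (cry1bb, cry2 and nfil3) and 2 of 20 in inhibitory neurons (cry1bb and nfil3), with medians of -0.20 and -0.16. In excitatory neurons ciarta missed only the log2 limit (-0.84, edgeR adjusted p 0.020). So did cry2 (-0.98, 0.0079) and bhlhe40 (-0.55, 0.044) in inhibitory neurons.

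**Figure D3:**
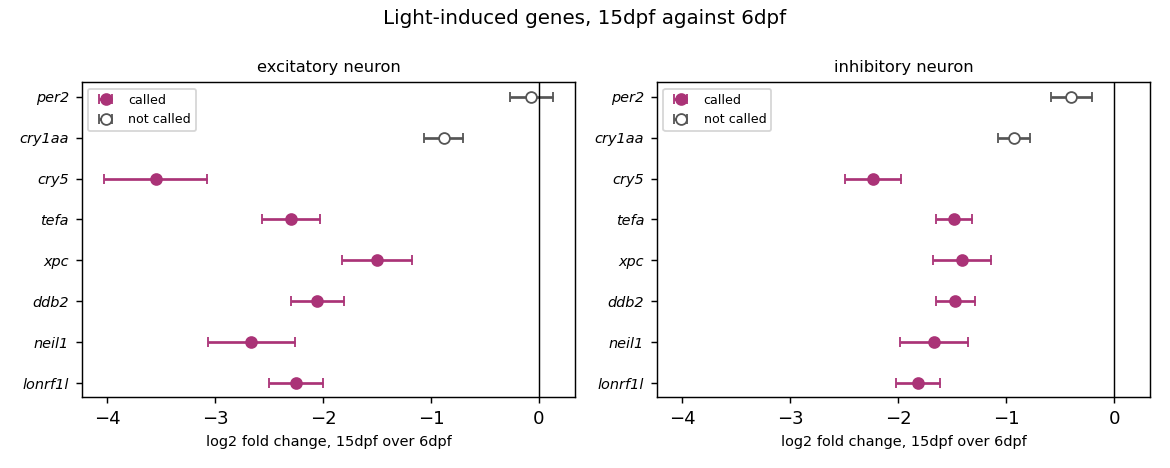
Log2 fold change at 15dpf against 6dpf, with its SE, of 8 light-induced genes in excitatory and inhibitory neurons, filled where the change passed the test. All but per2 and cry1aa passed in both classes, cry1aa missing only the log2 limit of 1, and the medians were -2.15 and -1.48.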

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

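The splits of the samples, the cluster and version tests, and the light and p53 lists were chosen after the results had been seen; the free RNA and handling tests were set before their values were looked at.

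Of 127 groups of 4 to 10 samples tested for a sample far from the others, 7 held one, and chance gives about 1 in 20. Mural cells made up 0.247% of cells in 15dpf sample 3, against 0.447% to 0.474% in the other 3. In radial glia abca1a stood at 5.63 log2 CPM in 6dpf sample 4 (others 6.64 to 6.82) and cbsb at 5.37 (others 6.81 to 7.03). In 15dpf sample 1 radial glia held rgs5b at 3.25 (0 in the others) and b2m at 0 (others 3.86 to 4.41). Excitatory neurons of that sample held cox8b at 6.12 (others 5.99 to 6.01), and its inhibitory neurons held dcps at 3.36 (others 3.59 to 3.61). A difference between groups also stood out: the change from 6dpf to adults differed between excitatory and inhibitory neurons for 892 genes, by a test of the interaction over whole classes.

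Immediate early genes were higher in adults than at 15dpf, and heat shock genes were higher at 15dpf than in adults. Free RNA as the source of the immediate early signal was argued against, since in each adult sample the 3 classes held from 5.56 to 7.13 times the summed level of the lowest class (committed precursors at the lowest ratio). For heat shock genes such ratios ran from 1.04 to 2.30 over the 15dpf samples, so free RNA stays open. Endothelial and mural cells together held 1.76 times as much of the immediate early list in adults and 1.92 times as much of the heat shock list at 15dpf. Both ratios lie between the 1.5 and 2 set beforehand, so handling and age cannot be told apart. A ratio of 2 or more could not have done so either, since a change with age allows it too. Neurons without a named transmitter were an exception, with 17495 CPM of immediate early genes at 15dpf and 13780 CPM in adults. The endothelial and mural group held 61 and 65 cells at 15dpf and 450 and 35 in adults, so its ratios also reflect that mix.

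At 15dpf against 6dpf, 1 of 35 splits of the samples (the real one) gave as many genes in radial glia (581, highest other 46). In neurons 100 of the 495 possible splits were run. Of these only the real one gave as many genes in excitatory neurons (948, highest other 65) and in inhibitory neurons (629, highest other 88). If the libraries are independent, these values argue against chance without excluding it. With alike libraries summed the real split gave the most genes in excitatory neurons (295, highest other 141) and inhibitory neurons (192, highest other 150). That is 1 of 21 splits, a share of 0.0476 and the smallest possible, so chance is argued against but not excluded. Radial glia (171, highest other 30, 1 of 15) had too few splits for a share under 0.05. A different mix of clusters as the whole cause at 15dpf was argued against, as each of 5 shared clusters called more genes (104 to 299) than other splits of its own libraries, counted singly, though in clusters 16 and 23 these reached 104 and 89 beside 134 and 104. The same holds for adults (198 to 410 genes called per cluster, at most 4 in other splits, of which there are only 15), while a finer mix within clusters was not tested, and within a class adult age cannot be told apart from file format. The software version as the whole cause in neurons was argued against at 15dpf by 729 genes in inhibitory neurons among the 3.1.0 libraries, while for radial glia (115 genes there, against 1 sample of 6dpf) it stays open.

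Light-induced genes moved with cry-dash, whose fall at 15dpf in inhibitory neurons led to that list. Their median log2 change was -1.48 in inhibitory and -2.15 in excitatory neurons, low enough for what was predicted of a difference in light or time of day at dissection. The list was chosen after results had been seen, so meeting that prediction is weak evidence. Core clock genes had medians of -0.20 in excitatory and -0.16 in inhibitory neurons, with 3 of 23 and 2 of 20 called lower. Single clock genes had changes of both signs, so these medians cannot tell whether time of day differed. The gene per2, a member of the light list, did not pass, which cannot separate light from time of day. A response of p53 to DNA damage was left undecided, with medians of -0.37 in excitatory and -0.39 in inhibitory neurons. Of the tested targets 2 of 7 were called lower in excitatory (bbc3 and tp53inp1) and 1 of 6 in inhibitory neurons (tp53inp1). In inhibitory neurons ccng1 was higher by 0.86 (edgeR adjusted p 0.011) and missed only the log2 limit of 1. Age stays open as a biological explanation, since light, time of day and age were not varied apart.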

How the results depend on the processing

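All values for summed alike libraries, the 3.1.0 libraries, 6dpf samples 6 and 7 left out, microglia with at least 5 cells and neurons by cluster number come from alternatives chosen after seeing the data. Of the values of comparisons under alternatives, 343 kept their direction and their side of the threshold or stayed within 1.5 times the count, 33 moved further, 6 were weaker and 1 was stronger. Of the 261 named genes and list examples, 130 kept direction and side under all alternatives run for them; single values were the same in 6019 cases, lost the threshold in 473 and changed sign in 5. RLE scaling and DESeq2 moved no count of genes by more than 1.5 times.

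Thinned to 1000 UMIs, which leaves fewer genes to test, radial glia gave 142 genes (15dpf against 6dpf) and 164 (adults against 15dpf), and excitatory neurons 621 at 15dpf. With no low-count filter, which tests more genes, the adult contrasts gave 918 in radial glia, 2268 in excitatory and 2462 in inhibitory neurons. The guard against free RNA, which tests fewer genes, gave 605 and 749 in excitatory neurons (15dpf, adults) and 1004 in adult inhibitory neurons. With at least 800 genes per cell the adult contrasts gave 1277 in radial glia and 968 in inhibitory neurons, and the cause was not tested. The radial glia class then held 2010 cells in place of 1301, though fewer cells were kept, so it took in other cells. With alike libraries summed, which leaves fewer samples, counts were 171 and 268 in radial glia, 295 and 841 in excitatory neurons, 192 in inhibitory neurons at 15dpf and 21 in microglia at 15dpf. For radial glia the summing left 2 samples of 15dpf but still 4 of 6dpf. It brought in 6dpf libraries 5, 6 and 7, which held 8, 14 and 8 such cells and were left out singly, so that count also reflects other libraries. Leaving out 1 sample each gave 823 to 1402 genes for adult excitatory neurons (823 without adult sample 1) and 1009 to 1566 for adult inhibitory neurons (1009 without adult sample 2). Radial glia gave no value at resolution 0.5, where too few larval cells fell in the class for the minimum of 20 per sample, and microglia gave none at the minimum of 20 cells. A lone sample was assumed to vary like the other stages. Within the 3.1.0 libraries, with 1 sample of 6dpf, radial glia gave 115 genes at 15dpf. Camera with an estimated correlation gave 0 of 102 list tests with an adjusted p under 0.05.

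The numbers 1 to 4 that 6dpf and 15dpf titles share did not pair the samples: a sample's own number was the best match in 1 of 4 cases per class, with correlations from -0.155 to 0.107. With the number as a replicate block radial glia gave 296 genes, excitatory neurons 798 and inhibitory neurons 580, and within the block the 15dpf share of microglia was 0.0543 points higher, that of proliferating progenitors changed by -2.92 points and that of cluster 28 by 0.0685 points, all 3 reversed; the cause was not tested.

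For class shares, 15dpf against 6dpf passed in 0 to 3 classes when 1 sample was left out (3 without 6dpf sample 7) and in 2 without 6dpf samples 6 and 7, which hold 271 and 294 unnamed cells. Adults against 6dpf passed in 8 classes with 4 adult libraries as samples, 6 at resolution 0.5, 5 with at least 800 genes and 9 with neurons by cluster number. Adults against 15dpf did not overlap in 6 classes with at least 800 genes. The inhibitory share differed by -4.96 points between 15dpf and 6dpf in the 3.1.0 libraries, by -3.64 (800 genes) and -2.70 (doublets kept) between adults and 15dpf, by -5.86 between adults and 6dpf with 800 genes, and by -16.5 to -15.2 with 1 sample left out; with 1 adult sample the smallest exact p is 0.111. The cycling share of adults differed from 15dpf by -37.3 points when cells were not thinned, by -58.3 points with 3 or more genes, by -34.6 points from 6dpf at resolution 0.5, and by -49.0 to -43.9 points with 1 sample left out.

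Other directions reversed, and the cause was not tested. At 15dpf against 6dpf the proliferating progenitor share changed by -3.60 points at resolution 0.5, -0.146 with 800 genes, -1.29 without 6dpf samples 6 and 7, and -0.433 to 1.23 with 1 sample left out; microglia by 0.0102 without samples 6 and 7; and radial glia by 0.0426 at resolution 0.5 and 0.257 in the 3.1.0 libraries. Adults against 15dpf gave -4.06 for excitatory neurons with doublets kept, 1.12 for inhibitory neurons and -2.04 for radial glia with 800 genes, and 1.71 (resolution 2) and 12.07 (doublets kept) for neurons without a named transmitter. Adults against 6dpf gave 5.71 for inhibitory neurons, -0.405 for microglia and -9.97 for radial glia with 800 genes, 0.323 (resolution 2) and 8.10 (doublets kept) for neurons without a named transmitter, and 0.149 for cluster 28 without samples 6 and 7. With doublets kept, the excitatory class held 23971 cells in place of 27587, and neurons without a named transmitter 10575 in place of 5620. Radial glia held 1301 cells in the main setting, 2010 with 800 genes and 517 at resolution 0.5. At resolution 0.5 proliferating progenitors held 3997 cells in place of 2759. Which cells moved between classes was not followed. In radial glia with 800 genes krt8 (-1.39), cldn19 (-0.35) and fosb (-0.72) reversed at 15dpf and tmsb (-0.39) in adults, and her6 (-0.66) reversed in adult excitatory neurons with doublets kept.

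Median depth per barcode was lowest at 6dpf. Thinned to 1000 UMIs, inhibitory neurons gave 481 genes at 15dpf and 1178 in adults and excitatory neurons 1031 in adults, all within 1.5 times the count.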

Other observations

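The clusters below stayed unnamed and were described after their genes had been seen. Cluster 28, led by epd and krt4, made up 2.91% of cells at 6dpf, 0.602% at 15dpf and 1.00% in adults. Cluster 31, led by si:ch211-80h18.1, CNDP1 and fabp7b, made up 3.67%, 0.201% and 0.254%, with 11.7% and 11.4% in 6dpf samples 6 and 7, and no cell among 12235 in adult sample 2. Cluster 38, led by si:ch211-214p16.1, ccl19a.1 and ccl33.3, made up 0.0868%, 0.0345% and 0.925%.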
